A study of Homo sapiens with 6 samples.

How the data were processed

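The series measured RNA of AGS cells on Affymetrix HuGene-1_0-st arrays, which read each gene with probes spread along its transcript and report 1 value per transcript cluster. The labels name 6 arrays, 3 of control cells and 3 of cells given celecoxib. The deposited table holds log2 expression values for 33297 transcript clusters in 6 columns, 1 per array. Per the submitters' processing notes, the authors made the values with RMA (background correction, quantile normalization and probe summary) in Affymetrix Expression Console 1.1. The probe-level settings are not given in the sources used here. Scanner files were not used here, so signal over background could not be set for single clusters. Slide and scan date are not given in the sources used here, so no batch was tested. The number of arrays limits the precision.

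Transcript clusters were named from the platform annotation. Of the 33297 clusters, 19460 had 1 gene symbol, 1754 had several and 12083 were unnamed here. The Entrez identifiers of 19429 of the 19460 were in a gene table of assembly GRCh38.p14, used for names and kinds of gene only, and 0 symbols changed. Clusters with 1 symbol were kept. Where a gene had several (769 genes), the cluster with the highest mean over the 6 arrays stood for it, which left 18417 genes. No filter on signal was applied in the main comparison. Arrays of this design cannot separate near-identical family members well, so values of REG1A and REG1B, of the AKR1C genes and of the MT1 genes carry that uncertainty.

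Groups were taken from the labels. A linear model compared the 3 celecoxib arrays with the 3 controls, gene by gene, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the 18417 genes. The threshold was an adjusted p of 0.05, and a second count also asked for a log2 difference of at least 1 in size. Errors given with a difference are standard errors from this fit, and all tests are two-sided. Every log2 difference is celecoxib minus control.

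Before the data were examined, 28 gene lists (633 genes) were fixed for a gastric carcinoma line under a COX-2 inhibitor. Of these genes, 569 were measured, and 27 lists had at least 5 measured members. Members of the list of mitochondrially encoded transcripts were not analysed here. Each list was tested with camera of limma at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation and the directional rotation test fry were alternatives. For single members, the count past the threshold when adjusted over the list alone is given beside that over all genes.

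The genes named were chosen by a rule also fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap. It leaves out symbols of uncharacterised loci, non-coding RNA, olfactory receptors, FAM, KIAA and TMEM genes, and symbols ending in P and a number, a pattern of pseudogenes. It adds up to 4 members of each list with the smallest adjusted p, up to 2 with the largest difference in lists with no member past the threshold, and PTGS1, PTGS2, CA2, CA9 and CA12, known protein targets of celecoxib. CA9 was not analysed here. The rule's symbol filter also removes the protein-coding genes MCTP1, CSRP1, TMEM45B and TMEM144, which passed the threshold and are named after their values were seen.

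Alternatives fixed before the data were examined were the mean of a gene's clusters, each cluster on its own, 2 filters on dim genes, 3 further normalizations, an intensity trend in the variance prior with and without a robust prior, array weights, the replicate number as a block, and leaving out each array. A filter kept genes with a mean above 6.785, the median of all clusters, or left out the dimmest 20% (below 5.629). Chosen after seeing the data were the level of small nuclear and nucleolar RNA as a covariate, protein-coding genes only, and all 33297 clusters tested together.

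The procedure was tested on 20 simulated data sets of the 18417 genes with 200 changed genes each. It recovered 75.9% of genes changed by 0.5 on the log2 scale, 99.5% at 1 and 100% at 2, with 5.97% false calls. A list shifted by 0.25 was called in 20 of 20 simulations. The simulated noise was independent between genes, so the simulations do not cover correlation within lists. Its variances were those that eBayes had already drawn towards a common value, so they were more alike between genes than the measured ones. The recovered shares may therefore be too high for the measured genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.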

Results

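Transcript levels were measured in AGS cells, an established line from a human gastric carcinoma, after exposure to celecoxib, a drug that inhibits the prostaglandin-producing enzyme cyclooxygenase-2 (COX-2, encoded by PTGS2). Cells were seeded and grown for 48 h, then kept for 24 h with 20 µM celecoxib or as untreated controls. Each group had 3 arrays, hybridised with product from 250 ng of total RNA. The labels call them biological replicates but also speak of pooling after the RNA quality check, without saying which wells each array holds. The p-values then measure only the spread between these samples, which may be technical. Celecoxib was dissolved in DMSO, and whether the controls received DMSO is not given in the sources used here, so the comparison is of celecoxib with its solvent against the labelled controls.

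The median log2 value of an array lay between 6.75 and 6.82. Pearson's r between pairs of arrays, across transcript clusters, ranged from 0.985 to 0.996. The first principal component held 44.9% of the variance and did not separate the groups, with controls at -8.08, -16.4 and 1.78 and celecoxib arrays at 23.9, -3.92 and 2.70. Celecoxib replicate 1 lay furthest from the rest on it.

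The first question was which genes changed with celecoxib. The largest falls were in CCN2 (connective tissue growth factor), which was 2.24-fold lower, TAGLN (transgelin, an actin-binding protein), 2.16-fold lower, EDN1 (the precursor of endothelin-1), 2.12-fold lower, and HEG1, a membrane protein of cell junctions, 2.06-fold lower. The largest rises were in APOA2, an apolipoprotein of high-density lipoprotein, at 2.13-fold, and MMP1, a collagenase, at 2.08-fold. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 1.81-fold. The cystine transporter SLC7A11 rose 1.52-fold, and the autophagy receptor SQSTM1 rose by 0.58 on the log2 scale. In all, 26 of 18417 genes passed an adjusted p of 0.05, 14 higher and 12 lower, and 6 of them changed at least 2-fold, 2 higher and 4 lower. At an unadjusted p under 0.05 there were 2083 genes, 1265 higher and 818 lower, where chance alone would give about 921. The 2 groups did not overlap in 2042 genes with higher values (11.1%) and 1465 with lower values (7.95%), where chance gives 10% for both directions together.

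Among the rises, APOA2 increased by 1.09 ± 0.15 on the log2 scale (SE, n = 3 per group, limma adjusted p = 0.0449) and MMP1 by 1.05 ± 0.10 (adjusted p = 0.0168). CYP1A1 rose by 0.86 ± 0.11, and IGFL4, a member of the insulin-like growth factor-like family, by 0.82 ± 0.09. SOAT1, which esterifies cholesterol, rose by 0.62 ± 0.08, SLC7A11 by 0.60 ± 0.06 and HSD17B11, a short-chain dehydrogenase, by 0.59 ± 0.07. SQSTM1, the arrestin-like ARRDC4 and CADPS2, a factor of dense-core vesicle release, each rose by 0.58, with standard errors of 0.07, 0.08 and 0.07. TTN, the gene of titin, rose by 0.56 ± 0.07. MCTP1, TMEM45B and TMEM144, named after their values were seen, rose by 0.68 ± 0.08, 0.69 ± 0.09 and 0.57 ± 0.06. The adjusted p of these 14 genes lay between 0.0168 and 0.0449.

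Among the falls, CCN2 differed by -1.16 ± 0.12 (SE, n = 3 per group, limma adjusted p = 0.0209), TAGLN by -1.11 ± 0.13, EDN1 by -1.08 ± 0.09 (adjusted p = 0.0124) and HEG1 by -1.04 ± 0.12. The keratin KRT80 differed by -0.90 ± 0.08, the transcription factor CREB5 by -0.88 ± 0.07 and the endothelial lipase LIPG by -0.70 ± 0.07. PHLDB2, a protein of the cell cortex, differed by -0.67 ± 0.08, and MYL9, a regulatory light chain of myosin, by -0.66 ± 0.07. DPYSL3 differed by -0.60 ± 0.07 and FSTL3, an activin-binding protein, by -0.50 ± 0.07. CSRP1, a LIM protein of the actin cytoskeleton named after its values were seen, differed by -0.53 ± 0.07. The adjusted p of these 12 genes lay between 0.0124 and 0.0426. For all 26 genes, the 3 celecoxib values lay on one side of the 3 control values.

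**Figure D1:**
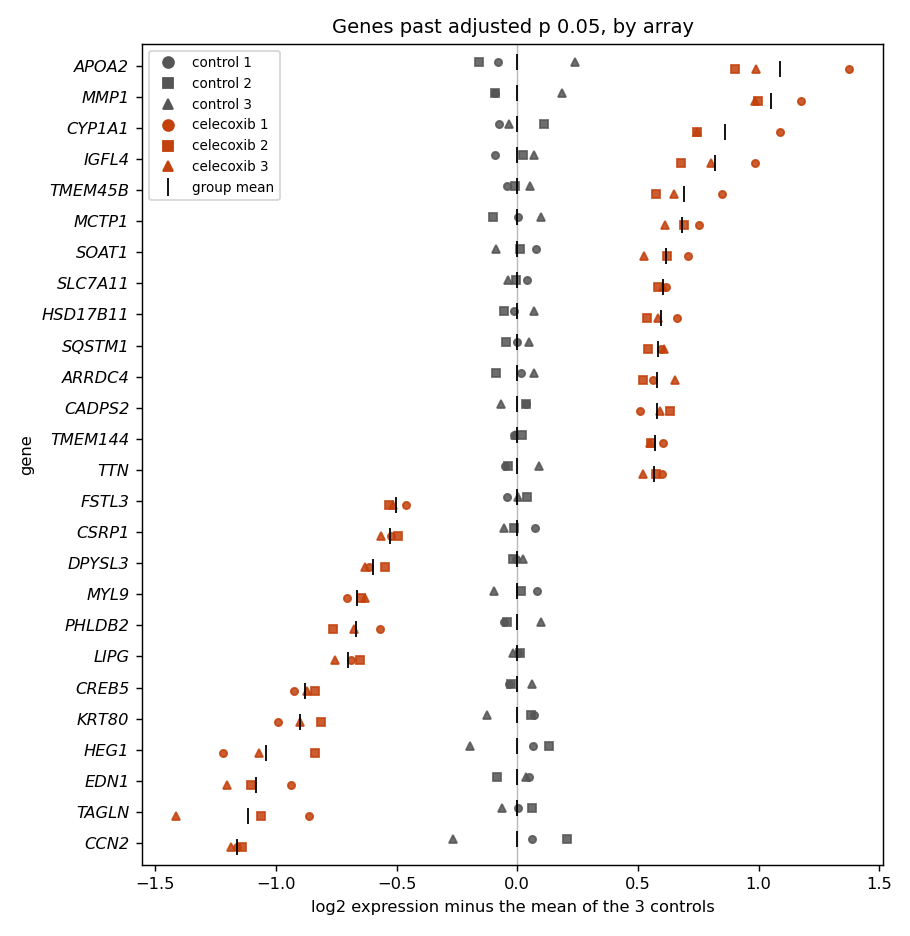
Log2 expression of the 26 genes past an adjusted p of 0.05, minus the mean of the 3 controls, per array; grey marks are controls, orange marks celecoxib arrays, and vertical bars group means. The means run from 1.09 for APOA2 to -1.16 for CCN2, with no overlap between the groups.

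The count of called genes rested on having all 6 arrays. It was 5 without control 3 and 1 without celecoxib 1, and limma called 0 without control 1, control 2, celecoxib 2 or celecoxib 3, where 1365, 1293, 2353 and 2102 genes had an unadjusted p under 0.05. It was also 0 when all 33297 clusters were tested together (2551 at an unadjusted p under 0.05, smallest adjusted p 0.0839), and it reached 177 with array weights.

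Levels of the drug's known targets were compared next. PTGS2 (COX-2) averaged 8.41 ± 0.06 in the controls and 8.40 ± 0.08 with celecoxib (log2, SD, n = 3), a difference of -0.02 with a 95% interval from -0.19 to 0.16 (limma adjusted p = 0.944). PTGS1 (COX-1) differed by -0.02, with an interval from -0.18 to 0.14 (adjusted p = 0.919). Of the carbonic anhydrases that celecoxib also binds, CA2 differed by 0.18 ± 0.07 (SE, adjusted p = 0.386) and CA12 by 0.08 ± 0.08 (adjusted p = 0.716), and CA9 was not analysed here. The list of 14 measured carbonic anhydrases was not called (camera adjusted p = 0.304). In it, CA13 differed by 0.36 ± 0.07, 1 member past the threshold when adjusted over the list alone and 0 over all genes. The 26 measured genes of prostaglandin and leukotriene metabolism were not called either (adjusted p = 0.769), with PTGER2 at 0.23 ± 0.07 and PTGER1 at -0.24 ± 0.09.

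Of the 27 lists tested, 13 were called by camera at the preset correlation, 8 higher and 5 lower. With an estimated correlation 0 were called, the smallest adjusted p being 0.174. Fry called 6, those of cholesterol synthesis, NRF2 targets, autophagy and lysosome, endoplasmic reticulum chaperones and degradation, NF-kappaB targets and p53 targets. The other 7 calls were lost under it.

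Genes of cholesterol synthesis and uptake fell as a list. Of 19 measured members (25 were fixed), 16 were lower, and the median difference was -0.25 (camera adjusted p = 4.59e-07; adjusted p = 0.174 with an estimated correlation). No member passed over all genes, and 10 did when adjusted over the list alone. HMGCS1, the enzyme that makes HMG-CoA, differed by -0.50 ± 0.07 (limma adjusted p = 0.0546), the sterol sensor partner INSIG1 by -0.43 ± 0.07, DHCR7, the last enzyme of one branch of the pathway, by -0.38 ± 0.06 and squalene epoxidase SQLE by -0.37 ± 0.07. The mean of the list was lower in all 3 celecoxib arrays than in all 3 controls.

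The fatty acid synthesis list was just past the threshold in the same direction, with 11 of 15 members lower and a median of -0.07 (camera adjusted p = 0.04996; adjusted p = 0.304 with an estimated correlation). When adjusted over the list alone, LPIN1, a phosphatidic acid phosphatase, was lower (-0.45 ± 0.09) and ME1, malic enzyme, was higher (0.43 ± 0.08). Over all genes 0 passed. ME1 was dim, with means of 4.41 in the controls and 4.84 with celecoxib, and both filters on dim genes left it out. FASN, the fatty acid synthase, differed by -0.61 ± 0.18 and ACACA by -0.25 ± 0.08, neither past the threshold. The call was lost without control 1 (adjusted p = 0.0664), control 2 (0.119), celecoxib 1 (0.0937) or celecoxib 3 (0.0987), and with the array's level of small nuclear and nucleolar RNA as a covariate (0.514). Without these arrays in turn the median did not shrink, at -0.090, -0.077, -0.102 and -0.084, and with the covariate it was -0.058. It held in 13 of 21 alternatives.

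Targets of NRF2, the transcription factor of the antioxidant response, rose as a list. Of 21 measured members (24 were fixed), 17 were higher, with a median of 0.16 (camera adjusted p = 4.35e-05; adjusted p = 0.174 with an estimated correlation). SLC7A11 passed over all genes, and 4 members passed when adjusted over the list alone. The other 3 were ME1, a dim gene that both filters left out, the ferritin light chain FTL (0.34 ± 0.07) and the quinone reductase NQO1 (0.32 ± 0.07). SQSTM1, counted in another list, is a known NRF2 target as well.

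Autophagy and lysosome genes rose as a list, with 14 of 20 measured members higher and a median of 0.19 (camera adjusted p = 1e-04; adjusted p = 0.174 with an estimated correlation). SQSTM1 passed over all genes and 5 members passed when adjusted over the list alone. Among these were WIPI1, a factor of autophagosome formation (0.37 ± 0.08), ATP6V1H, a subunit of the lysosomal proton pump (0.31 ± 0.08), and NEU1, a lysosomal sialidase (0.35 ± 0.09). CTSD, the protease cathepsin D, was the other member, at 0.25 ± 0.07.

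The list of mitosis genes fell, with 25 of 29 measured members lower and a median of -0.17 (camera adjusted p = 1.41e-07; adjusted p = 0.417 with an estimated correlation and 0.129 by fry). No member passed over all genes and 6 did when adjusted over the list alone. KIF20A, a kinesin of late mitosis, differed by -0.37 ± 0.08, the checkpoint kinase BUB1B by -0.30 ± 0.07, KIF23 by -0.33 ± 0.09 and CDC20 by -0.29 ± 0.08. The mean of the list overlapped between the groups, as celecoxib 1 lay above control 2. The list of DNA replication and E2F targets was not called (35 members, median -0.03, adjusted p = 0.297), but was called lower with array weights (0.0282) and with small RNA level as a covariate (0.0243). CDT1 and GINS1 of this list differed by -0.26 ± 0.09 and -0.22 ± 0.07, and GINS3 by 0.20 ± 0.08. Of its 35 members, 16 were higher and 19 lower.

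The list of endoplasmic reticulum chaperones and of degradation associated with that compartment rose. Of 23 members 17 were higher, with a median of 0.08 (camera adjusted p = 0.00628, and 0.174 with an estimated correlation). ERO1B, an oxidase of protein folding, was the 1 member past the threshold when adjusted over the list alone (0.52 ± 0.10), and 0 passed over all genes. The call was lost among genes above the median signal (adjusted p = 0.0566). SEL1L and HERPUD1, members for degradation, differed by 0.23 ± 0.07 and 0.27 ± 0.08. Among the chaperones, HSPA5 stood at 0.17 ± 0.07 and DNAJB11 at 0.15 ± 0.08. CALR (0.02 ± 0.07), HSP90B1 (-0.03 ± 0.06) and HYOU1 (-0.06 ± 0.10) were near 0, so the call is not a rise of chaperones as a whole. The integrated stress response list was not called (35 members, adjusted p = 0.491). It held SLC7A11, which rose, and the stress transcription factor DDIT3 at 0.66 ± 0.12 (limma adjusted p = 0.11), while 21 of its members, among them ASNS (-0.25 ± 0.09) and MARS1 (-0.21 ± 0.06), had negative differences. The heat shock list was not called (adjusted p = 0.962), and its median (-0.01) and mean (0.01) differed in sign. HSPA4L stood at 0.36 ± 0.09 in it and HSPB1 at -0.20 ± 0.07.

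**Figure D2:**
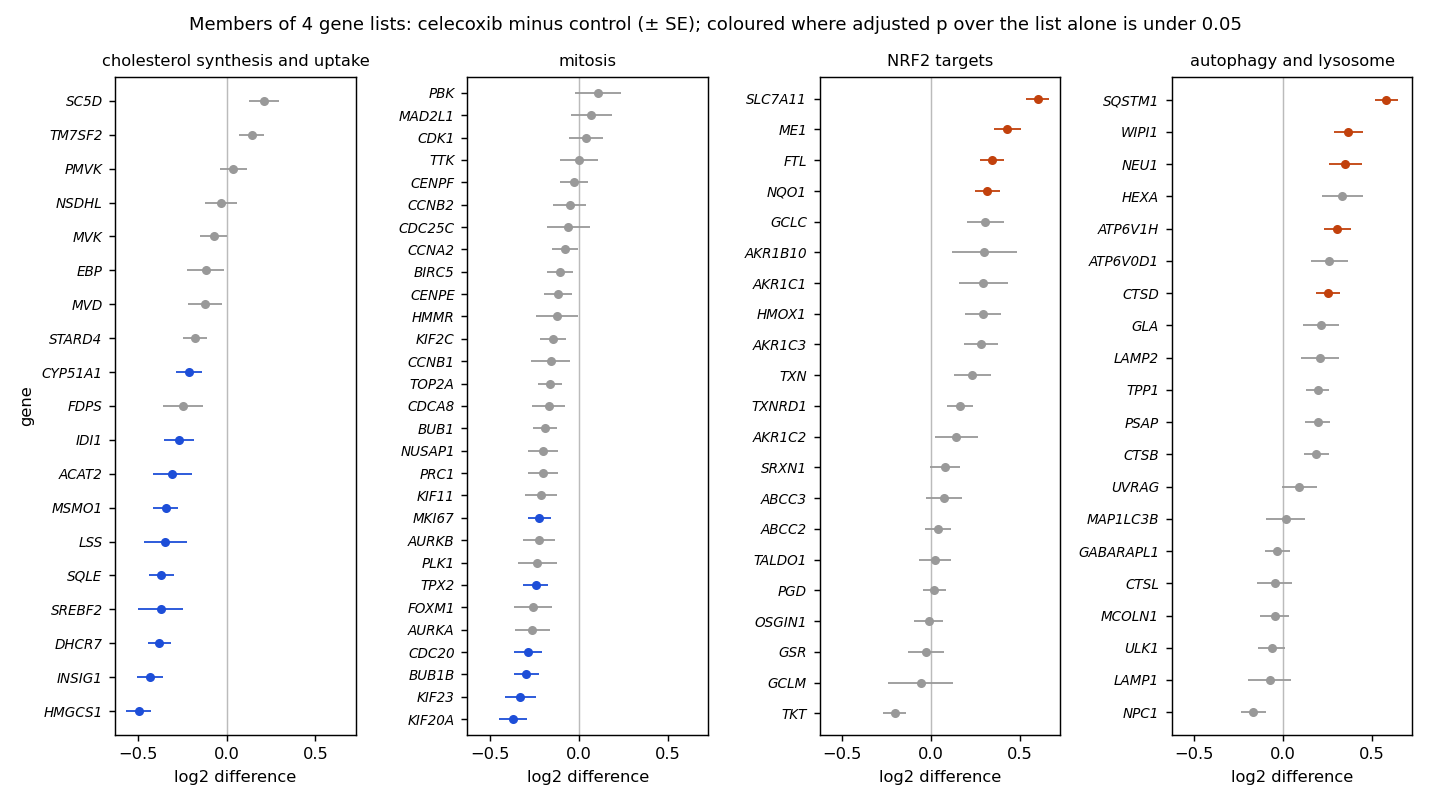
Log2 difference (celecoxib minus control) of each measured member of 4 gene lists; points are estimates, bars standard errors, and coloured points passed 0.05 when adjusted over the list alone. Of 19 cholesterol genes 16 lie below 0, of 29 mitosis genes 25, while 17 of 21 NRF2 targets and 14 of 20 autophagy and lysosome genes lie above 0.

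Targets of NF-kappaB and cytokines fell as a list, with 14 of 19 members lower and a median of -0.07 (camera adjusted p = 0.0109; adjusted p = 0.178 with an estimated correlation). The cytokine IL32 differed by -0.70 ± 0.12 (limma adjusted p = 0.0879) and was the 1 member past the threshold when adjusted over the list alone. TNFAIP2, IRF1 and TNFAIP3 differed by -0.34 ± 0.10, -0.28 ± 0.09 and -0.27 ± 0.09.

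The mesenchymal and matrix list fell, with 17 of 21 members lower and a median of -0.08 (camera adjusted p = 0.00895; adjusted p = 0.417 with an estimated correlation). Its strongest members went in opposite directions: the collagenase MMP1 rose and CCN2 fell, both past the threshold over all genes. When adjusted over the list alone, 3 members were lower and 1 higher. The matricellular gene CCN1, a relative of CCN2, differed by -0.66 ± 0.12 and THBS1, thrombospondin-1, by -0.52 ± 0.12. The call was lost without control 3 (adjusted p = 0.151) and with array weights (0.0914).

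The list of p53 targets was just past the threshold, with 15 of 23 members higher and a median of 0.06 (camera adjusted p = 0.04996; adjusted p = 0.303 with an estimated correlation). The stress cytokine GDF15 differed by 0.44 ± 0.07 (limma adjusted p = 0.0907), and RRM2B and SESN1 each by 0.26. These 3 members passed the threshold when adjusted over the list alone. The 8 lower members included DDB2 (-0.16 ± 0.06, groups not overlapping), BBC3 (-0.11 ± 0.08), BAX (-0.09 ± 0.07) and CDKN1A (-0.003 ± 0.115). MDM2 stood at 0.06 ± 0.07. The call was lost without control 3 (adjusted p = 0.204), celecoxib 2 (0.151) or celecoxib 3 (0.0920), and held in 10 of 21 alternatives. The list of apoptosis regulators was not called (24 members, adjusted p = 0.626). In it the pro-apoptotic BIK stood at 0.49 ± 0.09 (limma adjusted p = 0.0937) and the anti-apoptotic BCL2L1 at -0.30 ± 0.09. HRK, also pro-apoptotic, went the other way from BIK, at -0.19 ± 0.09 (limma adjusted p = 0.447). Of the 24 members, 10 were higher and 14 lower.

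The list of PPAR targets and fatty acid oxidation rose, with 12 of 18 members higher and a median of 0.05 (camera adjusted p = 0.0117; adjusted p = 0.304 with an estimated correlation). The electron transfer enzyme ETFDH differed by 0.53 ± 0.09, the acyl-CoA dehydrogenase ACADM by 0.35 ± 0.09, HADHB by 0.36 ± 0.11 and the lipid droplet protein PLIN2 by 0.31 ± 0.08. These 4 passed when adjusted over the list alone and 0 over all genes. The call was lost without celecoxib 1 (adjusted p = 0.0522) and with the level of small nuclear and nucleolar RNA as a covariate (0.319). The median itself moved little, to 0.057 and 0.047.

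The lists of oxidative phosphorylation, metallothioneins and interferon-stimulated genes were called higher, with medians of 0.14, 0.11 and 0.09 (camera adjusted p = 0.00172, 0.0445 and 0.0168; adjusted p = 0.543, 0.543 and 0.496 with an estimated correlation). No member passed over all genes or over the list alone. The members with the smallest p were COX6C (0.31 ± 0.12) and NDUFS1 (0.21 ± 0.07) of the respiratory chain, MT2A (0.17 ± 0.07), and OAS1 (0.25 ± 0.08) and IFI44L (0.21 ± 0.07). In each list celecoxib 1 had the highest mean and the groups overlapped. Without celecoxib 1 the adjusted p was 0.124 for oxidative phosphorylation, 0.175 for metallothioneins and 0.124 for interferon-stimulated genes. The metallothionein call was also lost without control 1 (0.0763) or control 2 (0.147), and the interferon call without control 2 (0.147). Over all alternatives the metallothionein call held in 11 of 21 and the interferon call in 14 of 21. Small nuclear and nucleolar RNA moved with these lists: the median of 195 such genes was 7.11, 6.98 and 7.13 in the controls and 7.49, 7.21 and 7.17 in the celecoxib arrays, and with this level as a covariate the 3 medians turned negative.

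The xenobiotic metabolism list was not called (16 members, adjusted p = 0.0788), but was called higher above the median signal (0.00325), without the dimmest 20% of genes (0.0176) and without celecoxib 2 (0.0475). CYP1A1 passed over all genes. When adjusted over the list alone, TIPARP, another target of the aryl hydrocarbon receptor (0.33 ± 0.09), and CYP2S1 (0.27 ± 0.08) passed with it. The gastric and intestinal epithelium list was not called (23 members, adjusted p = 0.841). The mucin MUC13 stood at 0.53 ± 0.08 and the microvillus protein VIL1 at -0.47 ± 0.08, the 2 members past the threshold when adjusted over the list alone, in opposite directions.

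Other lists were not called. The adjusted p was 0.202 for immediate early genes (DUSP1 -0.26 ± 0.07, JUN -0.32 ± 0.12, DUSP6 0.17 ± 0.08), with 9 higher and 13 lower. These were called lower without celecoxib 2 (0.0336) and had an adjusted p of 0.734 without celecoxib 1. For Wnt targets the adjusted p was 0.235 (AXIN2 -0.36 ± 0.16). It was 0.281 for hypoxia and glycolysis (ALDOC -0.51 ± 0.14, SLC2A3 -0.28 ± 0.08, P4HA1 0.30 ± 0.10), with 8 higher and 16 lower. It was 0.769 for ribosome biogenesis (WDR12 0.21 ± 0.08, DDX21 -0.18 ± 0.07) and for DNA repair (RPA2 0.46 ± 0.13, ATM 0.29 ± 0.08), whose median (-0.02) and mean (0.03) differed in sign. The 22 measured markers of fibroblasts, blood, endothelial and other cell types did not shift together (median -0.01, adjusted p = 0.769), with LUM at 0.24 ± 0.10 and COL1A1 at -0.12 ± 0.07.

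**Figure D3:**
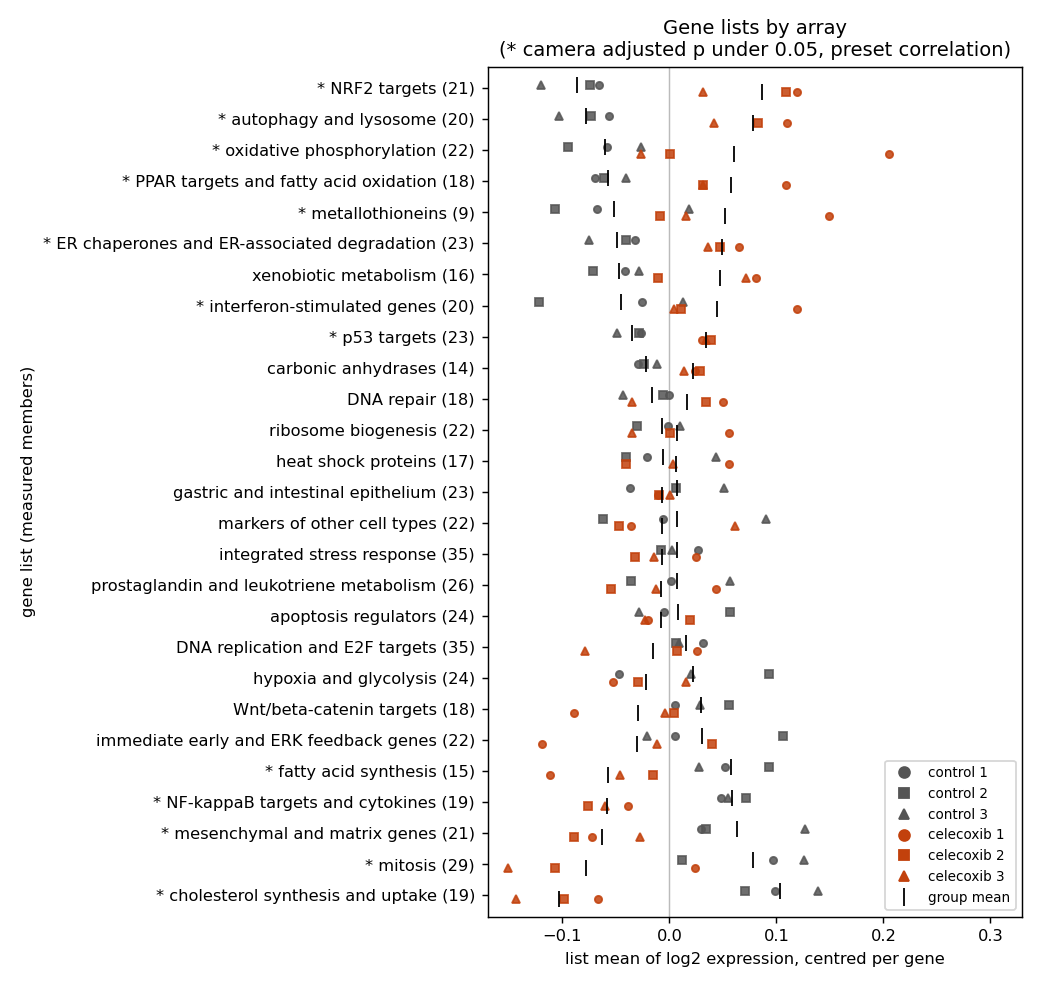
Mean of each of the 27 gene lists per array, in log2 expression centred per gene over the 6 arrays; grey marks are controls, orange marks celecoxib arrays, vertical bars group means, and a star marks the 13 lists called by camera at the preset correlation. NRF2 targets stand highest with celecoxib (group mean 0.09 against -0.09 in controls) and cholesterol genes lowest (-0.10 against 0.10).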

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

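The direction of each of the 26 called genes held in every alternative, but the counts moved. As the groups of these genes did not overlap, leaving out an array could not turn a direction and is no support for it. Instead of 26 genes, the count was 76 above the median signal, 59 without the dimmest 20%, 40 after quantile normalization again, 47 after cyclic loess, 69 with an intensity trend with or without a robust prior, 177 with array weights and 0 by limma with the replicate block (2448 at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 5 genes, 0 to 3 of them at least 2-fold (6 with all arrays), and 8 to 14 lists. The replicate block also gave 0 genes of at least 2-fold, but 12 lists. Whether the replicate numbers pair the samples stays open. Same-numbered arrays correlated at -0.017, 0.494 and 0.012 in their deviations from the group means. Only replicate 2 of both groups correlated best with its own number, and 3 arrays per group are too few to decide. Median centring gave 28 genes, 18 higher and 10 lower, against 14 and 12. Other alternatives gave 25 to 28 genes. The number of lists (13) fell to 0 with an estimated inter-gene correlation and to 6 with fry.

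Chosen after seeing the data, the small RNA level as a covariate left 1 gene, also the 1 of at least 2-fold, and 9 lists. It differs between the groups itself. As a covariate it turned the medians of oxidative phosphorylation (-0.031), metallothioneins (-0.033) and interferon-stimulated genes (-0.014). It also ended the calls of PPAR targets (camera adjusted p = 0.319) and fatty acid synthesis (0.514), and called DNA replication lower (0.0243). The medians of PPAR targets (0.047 against 0.050) and fatty acid synthesis (-0.058 against -0.068) moved little. The cause was not tested. Protein-coding genes only gave 49 genes, and all 33297 clusters gave 0. Both settings change the number of tests and also refit the variance prior, so unadjusted p-values change too. In the fit of all clusters, 1642 clusters with 1 symbol had an unadjusted p under 0.05, against 2162 when tested without the others. The number of tests and the prior were not tested apart. The cause of the other shifts was not tested, except that fewer arrays leave less precision. The lists of cholesterol synthesis, NRF2 targets, autophagy and lysosome, and NF-kappaB targets were called in 20 of 21 alternatives, all but the estimated correlation. Other alternatives ended these calls, by adjusted p. Above the median signal they were endoplasmic reticulum chaperones and degradation (0.0566), p53 targets (0.195), metallothioneins (0.1345) and interferon genes (0.0566). Without the dimmest 20% they were p53 targets (0.1002) and metallothioneins (0.0503), after quantile normalization again p53 targets (0.0784) and metallothioneins (0.0573), and after cyclic loess p53 targets (0.0967). With array weights they were p53 targets, interferon genes and mesenchymal genes (each 0.0914), metallothioneins (0.0532) and fatty acid synthesis (0.0546). The p53 call was also lost with the replicate block (0.0641) and among protein-coding genes (0.0522). Results that were not called changed sign in 36 pairs of a list and an alternative and in 13 pairs of a gene and an alternative. Signal over background was not set, so how far dim genes limit these counts is open.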

Other observations

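The tests of mitosis genes, small RNA and fibroblast transcripts, the lists of secretory, cytoskeletal and YAP target genes and the genes named in these paragraphs were chosen after the results were seen.

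Several genes of secreted and surface proteins of intestinal or hepatic type had positive differences that missed the threshold. REG1A and REG4, regenerating family lectins, stood at 0.74 ± 0.12 and 0.67 ± 0.11 on the log2 scale (celecoxib minus control, SE, n = 3 per group; limma adjusted p = 0.0896 and 0.0808). Complement C5 stood at 0.59 ± 0.08 (adjusted p = 0.0517), CEACAM5, the carcinoembryonic antigen, at 0.52 ± 0.08 (adjusted p = 0.0561). The fibrinogen chains FGA and FGG, further from the threshold, stood at 0.44 ± 0.10 and 0.40 ± 0.11 (adjusted p = 0.229 and 0.275). The remaining chain, FGB, stood at 0.11 ± 0.12 (adjusted p = 0.731) with overlapping groups. The groups did not overlap for REG1A, REG4, C5, CEACAM5, FGA and FGG. Of 27 genes of this kind listed after these values were seen, 19 were higher (camera adjusted p = 1.07e-07; adjusted p = 0.193 with an estimated correlation), which is not independent evidence of their direction. The other 8 were lower, among them FABP2 (-0.19 ± 0.15), APOB (-0.021 ± 0.073), SERPINA1 (-0.0013 ± 0.0907) and APOA1 (-0.0009 ± 0.0840). TXNIP, a glucose-responsive relative of ARRDC4, stood at 0.48 ± 0.07 (adjusted p = 0.0546).

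Several of the called falls, CCN2, TAGLN, MYL9 and CSRP1, are genes of the actin cytoskeleton or targets of the coactivator YAP. Of 33 measured genes of the actin cytoskeleton and contractility, 30 were lower, among them VCL (-0.48 ± 0.08), TPM4 (-0.47 ± 0.08), MYH9 (-0.70 ± 0.15) and ACTN1 (-0.39 ± 0.09). Of 25 YAP targets, 23 were lower, among them ANKRD1 (-0.58 ± 0.10). The camera adjusted p, over the lists chosen afterwards alone, was 2.58e-15 for the actin list and 1.26e-07 for the YAP targets. With an estimated correlation it was 0.00988 and 0.0159. Both lists were written after the falls were seen and are not independent evidence. Under 3 other normalizations the median change of the called members was at weakest -0.85, against -0.89. These were applied to values already quantile normalized and cover the called members only, so they cannot test the authors' normalization. Fibroblast transcripts did not fall as a list: the 9 had a median difference of 0.02 (camera adjusted p = 0.982). Those above the median signal, COL1A1 (-0.12 ± 0.07) and PDGFRA (0.00 ± 0.07), had one of -0.0600. LUM (mean 2.80 in controls, 3.04 with celecoxib) and DCN (3.51 and 3.53) lay near the lowest signals in both groups. In an established line these values are a weak test of a share of fibroblasts, and no conclusion is drawn from them. An effect of celecoxib or its solvent, the authors' normalization, pooling and an unlabelled batch stay open and were not tested apart.

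The lower mitosis genes did not rest on 1 array, since the list's median stayed below 0 without each array in turn, at highest -0.14. The gap between the group means was 2.04 within-group SDs with overlapping arrays, so the spread between arrays within a group stays open as an explanation. Mitosis genes move together (estimated inter-gene correlation 0.484), so a difference in growth between wells could give the same list result as the drug, and these tests do not separate them.

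Small nuclear and nucleolar RNA was higher in the celecoxib arrays, with a median difference of 0.18 over 195 genes. Without celecoxib 1 it was 0.0967, smaller but in the same direction, so neither celecoxib 1 alone nor celecoxib can be singled out. Its bootstrap SE over genes, 0.0115, does not measure the spread between arrays. The array medians of celecoxib 2 and 3 were 7.21 and 7.17, against 7.11, 6.98 and 7.13 in the controls. These transcripts carry no poly(A) tail, and differences in RNA preparation were not tested.

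All 10 splits of the 6 arrays into 3 and 3 were fitted. The real split gave 26 genes past the threshold, 6 of them changed at least 2-fold, and 13 lists, and the highest of the others gave 0, 0 and 7. In each case 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05. By unadjusted p under 0.05, the split that sets control 1, control 2 and celecoxib 2 against the rest gave 2713 genes against 2083 in the real one, a structure of the samples that follows the first principal component rather than the labels.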
